A study of Rattus norvegicus with 12 samples.

How the data were processed

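Adrenalectomized Sprague-Dawley rats aged 8 to 10 weeks, the females in diestrus, received vehicle or dexamethasone by intraperitoneal injection and liver was taken 6 h later, per the labels' protocols. RNA of 3 animals was pooled per array, and 500 ng of it was labelled with Cy3 and hybridized to single-colour Agilent whole-genome rat arrays, per the labels' protocols. The authors extracted spot intensities with Agilent Feature Extraction 9.1, and the deposited scanner files name version 9.1.3.1 with protocol GE1-v5_91_0806, per the file headers. The deposited value table holds log10 intensities of 41012 probes, with array medians from 1.49 to 1.52 and 195 missing values. How the authors scaled that table is not stated. Its values correlate with the log10 of the deposited processed signals at 0.996 or more, with slopes from 0.916 to 1.03 and shifts from -0.06 to 0.17, and it was used only as an alternative source.

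The deposited scanner files of all 12 arrays were reprocessed from the background-subtracted, detrended signal that Feature Extraction gives in arbitrary intensity units. The signal was taken to log2, and the 75th percentile of the non-control spots of each array was subtracted. The spots that the scanner software flagged as outliers within replicated features or of uneven signal (211 over all arrays) were set to missing, no spot was saturated, and spots of a probe were averaged (263 probes are printed 10 times, and 1639 control spots were left out). Probes well above background on at least 3 of 12 arrays, with at least 2 usable arrays in every group, were kept, and the brightest such probe stood for its gene. That left 24298 genes, 12179 of them with a gene symbol, and 116 of 291576 values missing. Of 41012 probes, 20369 were matched to a reference gene by accession, gene identifier, current symbol or older symbol, and 20643 kept the name in the file, most of which name transcripts without a symbol. Symbols are those of the reference gene table, and no coordinates were used.

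A linear model with a mean for each of the 4 groups was fitted to every gene with limma 3.58.1 under R 4.3.3 (statmod 1.5.0, and data.table in version 1.17.8; figures with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15). The model had 8 residual degrees of freedom and empirical Bayes added 2.39. The 5 contrasts were dexamethasone minus vehicle in males, the same in females, the female minus the male effect (the interaction), and female minus male after vehicle and after dexamethasone. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Of the called genes, all arrays of the compared groups were free of overlap for 4873 of 4895 genes in males, 5883 of 5919 in females and all 415 and 561 of the sex differences. With 3 arrays against 3, chance alone frees 10% of genes from overlap. A gene below background on every array of a group received a lower bound of its fold, set with the dimmest value well above background on each array of that group.

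Gene lists of hepatic pathways, cell-type markers, sex-biased genes and sex chromosome genes were fixed before the data were examined, together with the rule for naming genes. That rule names 13 genes chosen in advance, the 10 largest called changes in each direction per contrast among genes with a symbol whose arrays do not overlap, and up to 4 called members per list. A gene called in opposite directions in the sexes and the other-sex values of some named genes are given in addition. Lists with at least 5 measured members, 29 in number, were tested in all 5 contrasts (145 tests) with camera at its preset correlation of 0.01, adjusted within each contrast. Camera was also run with the correlation estimated from the residuals, and members were adjusted a second time over the list alone. A list of 4 sex chromosome genes was not tested. Different probes of a gene were called in opposite directions for 3 genes in males and 7 in females, Gas6 and Them5 among them.

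The pipeline was tested on simulated data, in 5 simulations with 200 of 24298 genes changed in males only. It recovered 0.597% of genes changed 1.5-fold, 13.1% of those changed 2-fold and 67.0% of those changed 4-fold in the male contrast, and 0%, 0.299% and 33.0% in the interaction, none in the wrong direction. Over the 5 simulations 21 unchanged genes were called in the male contrast and 7 in the interaction. For lists, 30 genes per simulation were raised in females after dexamethasone only, and in the female contrast every such list was called (5 of 5) and no unshifted list (0 of 100). The simulated genes varied independently of each other, so this says little about false list calls among correlated genes. On the real arrays, redrawn treatment labels called a median of 14 lists in males and females, but such draws keep part of the treatment contrast.

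Slides were read from the array barcodes and scan days from the headers. Slide 1 held male vehicle 2 and male dexamethasone 1, slide 2 male dexamethasone 2 and female vehicle 1 and 2, slide 3 male vehicle 1, slide 4 female dexamethasone 1 and 2 and slide 5 replicate 3 of each group. Slides 1 and 2 were scanned on the same day and the others on days of their own. The 75th percentile of signal was 155 to 196 on slide 5 and 194 to 279 on the other slides. Residuals of arrays from different groups correlated with a median of 0.27 on the same slide and -0.01 on different slides. Slide was therefore treated as a batch in alternative runs, while the main fit has no term for it. Values with slide as a fixed block come from a model with 4 residual degrees of freedom, and values within slide 5 rest on a single array per group and have no test. The correlation within slides, estimated for a random block, was 0.512.

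Alternatives chosen before the data were examined were quantile normalization, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, a filter at 6 of 12 arrays, flagged spots kept, the mean of all probes of a gene, every probe on its own, slide as a fixed or random block, replicate number as a block, scan day as a block, eBayes with trend and robust, only the groups of the comparison in the fit, a threshold of 1.5-fold, and leaving out each array in turn. A run on the 8 arrays not on slide 5 was added after the data were seen. Group labels were redrawn over all 10 splits of 6 arrays for simple contrasts and over 100 draws for the interaction and for both sexes together. Results for some genes are not reported here.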

Results

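The livers of adrenalectomized male and female rats were compared 6 h after a single injection of vehicle or of dexamethasone, a synthetic glucocorticoid, at 1 mg/kg. The series asks which hepatic genes glucocorticoids regulate differently in the sexes. There were 4 groups, vehicle or dexamethasone in either sex, of 3 arrays each. Every array carried RNA pooled from 3 animals, 9 animals per group, so each p-value below rests on the spread among arrays of pooled RNA and says nothing about single animals. In the main fit, which has no slide term, that spread also holds differences between slides, and arrays sharing a slide count as independent. Between 53.0% and 69.7% of the spots of an array stood well above background (median 63.4%). The 4 arrays of slide 5, which carried replicate 3 of every group, were dimmer (53.0% to 61.8%) than the other 8 (62.7% to 69.7%). In all, 24298 genes were measured, and the number of arrays, 3 per group, limits precision. Slide 5 alone held all 4 groups and the remaining groups were spread unevenly over slides 1 to 4, so values with slide as a block, and values within slide 5, are given beside the results. The values in brackets after a gene are log2 differences: each is a difference of group means of normalized log2 intensities ± SE, with 3 arrays per group. In 5 named genes a flagged spot was left out and 2 arrays remained in a group: Got1 in males after dexamethasone, Fkbp5 and Ces2c in females after dexamethasone, and Cyp2c11 and Mup4l1 in males after vehicle. For a gene lying below background in 1 of the compared groups only a lower bound of the fold is given, written as "at least". Where leaving out a single array ended a call, the highest adjusted p reached is given with the array whose omission gave it.

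In male liver dexamethasone raised the classical glucocorticoid-responsive genes within 6 h. Fkbp5, whose product is a co-chaperone that restrains the glucocorticoid receptor, rose 18.0-fold (4.17 ± 0.18, adjusted p = 3.09e-06). Tsc22d3, encoding the anti-inflammatory mediator GILZ, rose 9.20-fold (3.20 ± 0.24), the clock component Per1 8.22-fold (3.04 ± 0.17) and tyrosine aminotransferase, Tat, 5.51-fold (2.46 ± 0.32, adjusted p = 4.29e-04). The glucocorticoid receptor's own transcript, Nr3c1, fell by 1.30 ± 0.17 on the log2 scale. Across the genome 4895 of 24298 genes differed from vehicle in males (limma), 2269 higher and 2626 lower, and 3016 of them differed at least 2-fold.

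Among the largest increases in males, Slc5a11, a sodium and myo-inositol cotransporter, rose at least 63.9-fold, the synaptic calcium sensor Doc2a at least 58.9-fold, the tektin-like gene Tekt5l1 at least 44.4-fold, Gucy2c, the guanylin receptor, at least 26.6-fold, the calcium-binding protein gene Gca at least 23.8-fold and mitochondrial arginase, Arg2, at least 12.5-fold. Increases of measurable size in both groups included the carboxylesterase Ces2c (6.23 ± 0.37), aspartoacylase, Aspa (5.71 ± 0.39), the bicarbonate transporter Slc4a8 (5.58 ± 0.19, adjusted p = 5.90e-07) and the glycosyltransferase B3galnt1 (5.29 ± 0.36). The largest decreases comprised the chemokine genes Cxcl10 (at least 9.40-fold lower, adjusted p = 1.13e-05) and Cxcl1 (-4.10 ± 0.89). The inflammasome sensor Nlrc4 (-4.38 ± 0.57) and the oxidative stress response gene Osgin1 (-5.04 ± 0.30) fell as well, as did a subunit gene of soluble guanylate cyclase, Gucy1b2 (-5.33 ± 0.43), and the fasting hormone gene Fgf21 (-4.56 ± 0.91, adjusted p = 0.00555). Also among them were Cyp26b1, which clears retinoic acid (at least 12.5-fold lower), the lectin gene Chodl (at least 3.75-fold lower), the exchange factor Arhgef19 (-3.85 ± 0.45) and the homeobox gene Meox2 (-3.77 ± 0.51). All 115 genes named or nameable for this comparison kept their direction with slide as a block (107 were still called), within slide 5 and within slide 1. As the groups of nearly all called genes do not overlap, agreement within a slide was largely fixed in advance and is no test. With the block, Fkbp5 stood at 4.24 and Tat at 2.31, and within slide 5 at 4.38 and 2.15.

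As lists, genes of glucose and amino acid metabolism rose in males. Among the 31 measured glucocorticoid-induced genes, 17 rose, 2 fell and 12 were not called, with 17 and 2 adjusted over the list alone. The median was 1.02 (adjusted p = 5.28e-07, adjusted p = 0.00689 with an estimated correlation). Zbtb16, a transcriptional repressor induced by steroid hormones, rose by 4.99 ± 0.84, whereas the glucose-sparing kinase gene Pdk4 fell (-3.48 ± 0.42) although glucocorticoids are known to induce it. Of the 32 genes of gluconeogenesis and amino acid catabolism, 12 rose, 2 fell and 18 were not called, with 16 and 2 adjusted over the list alone. Their median lay at 0.53 (adjusted p = 2.99e-05, adjusted p = 0.216 with an estimated correlation). The aspartate aminotransferase Got1 (3.59 ± 0.19), the tryptophan dioxygenase Tdo2 (3.23 ± 0.18), serine dehydratase, Sds (2.75 ± 0.38), and the bifunctional glycolytic regulator Pfkfb1 (2.63 ± 0.31) rose. Pck1, the gluconeogenic carboxykinase and a textbook glucocorticoid target, was not called (-0.90 ± 0.40, adjusted p = 0.146). With slide as a block it lay at -1.16, adjusted p = 0.0205, and within slide 5 at -0.62. The medians of these lists were 0.88 with slide as a block and 1.17 within slide 5 for the former and 0.60 with slide as a block and 0.47 within slide 5 for the latter.

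Inflammatory, interferon and antigen-presentation genes fell in males. Interferon-response genes shifted most: of 30 measured, 1 rose, 19 fell and 10 were not called, with 1 and 22 adjusted over the list alone. The list's median was -1.48 (adjusted p = 2.82e-09, adjusted p = 0.0650 with an estimated correlation). The median was -1.06 with genes below background set at their bound, and -1.17 with slide as a block and -1.20 within slide 5. The immunity-related GTPases Igtp (-3.66 ± 0.29) and Irgm (-2.98 ± 0.41) fell, while the viral RNA sensor Ifih1 went against the list and rose (4.11 ± 0.21). The receptor-transporting protein gene Rtp4, a member of the female-biased list, fell too (-2.99 ± 0.27). Inflammatory mediators numbered 33, 3 higher, 19 lower and 11 not called, with 5 and 19 adjusted over the list alone. The median change was -0.99 (adjusted p = 1.49e-06, adjusted p = 0.0650 with an estimated correlation). Il1b fell (-2.37 ± 0.30), as did the monocyte chemoattractant Ccl2 (at least 3.08-fold lower). Zfp36, whose product destabilizes inflammatory mRNAs and which belongs to the immediate early list, rose (2.02 ± 0.54). Of 24 antigen-presentation genes, 0 rose, 11 fell and 13 were not called, with 0 and 14 adjusted over the list alone. Together they had a median of -0.87 (adjusted p = 6.21e-06, adjusted p = 0.0122 with an estimated correlation). Those that fell included the peptide transporter Tap1 (-1.65 ± 0.24), the class I gene RT1-N3 (-1.74 ± 0.33), the class II gene RT1-Da (-1.50 ± 0.30) and the invariant chain Cd74 (-1.42 ± 0.30). Medians stood at -0.96 with slide as a block and -1.07 within slide 5 for the mediators and at -0.94 with slide as a block and -0.72 within slide 5 for antigen presentation. The call of Zfp36 (0.0837 without male vehicle 3) was lost when a single array was left out.

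Leukocyte markers moved in the same direction in males. Of 16 T and NK lymphocyte markers, 1 rose, 6 fell and 9 were not called, with 1 and 9 adjusted over the list alone. The median log2 change was -0.84 (adjusted p = 0.00167, adjusted p = 0.220 with an estimated correlation). Those that fell included granzyme A, Gzma (-1.97 ± 0.23), the NK receptor Klrb1a (-1.36 ± 0.34), Cd3g (-1.33 ± 0.32) and Cd8a (at least 2.84-fold lower). Markers of B and plasma cells, 5 in number, gave 0 higher, 3 lower and 2 not called, with 0 and 3 adjusted over the list alone. Their median stood at -1.05 (adjusted p = 0.0452, adjusted p = 0.216 with an estimated correlation). Cd79b fell (-2.28 ± 0.58) and so did the immunoglobulin joining chain Jchain (-2.05 ± 0.63). Of 16 Kupffer cell and macrophage markers, 0 rose, 2 fell and 14 were not called, with 0 and 0 adjusted over the list alone. As a list they had a median of -0.54 (adjusted p = 0.0466, adjusted p = 0.748 with an estimated correlation). Members that fell were Aif1 (-1.23 ± 0.38) and Tyrobp (-1.02 ± 0.28). Neutrophil markers, 7 measured, were 0 higher and 3 lower (median -1.09, -1.02 with the block, -1.94 within slide 5, adjusted p = 0.0869), S100a8 among them (-2.64 ± 0.61). Bile duct markers fell as a list with a median of -0.68 (adjusted p = 0.00803, adjusted p = 0.138 with an estimated correlation). Of 13 measured, 0 rose, 3 fell and 10 were not called, with 0 and 4 adjusted over the list alone, the fallen ones including the keratins Krt18 (-1.58 ± 0.27) and Krt8 (-1.37 ± 0.28). Medians with slide as a block and within slide 5 lay at -0.81 and -0.68 for T and NK markers, at -0.97 and -1.92 for B and plasma cells, at -0.62 and -1.16 for Kupffer cells and at -0.93 and -0.72 for bile duct cells. The Kupffer result was lost without male vehicle 2 (adjusted p = 0.161), male vehicle 3 (0.0808), male dexamethasone 2 (0.128), male dexamethasone 3 (0.376) or female vehicle 3 (0.0532). That of B and plasma cells was lost with the slide block (adjusted p = 0.0867) and without male vehicle 1 (0.0798), male vehicle 2 (0.0527), male vehicle 3 (0.0542) or male dexamethasone 3 (0.0968). Lost in the same way were the calls of Cd79b (0.0720 without male vehicle 3), Jchain (0.146 without male dexamethasone 2), Aif1 (0.142 without male dexamethasone 3), Tyrobp (0.0943 without male vehicle 3), Cd3g (0.0536 without male dexamethasone 1) and Klrb1a (0.0578 without male vehicle 2).

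Lipid, bile acid and zonation genes also responded in males. The bile acid list, 25 measured, gave 3 higher, 11 lower and 11 not called, with 3 and 12 adjusted over the list alone. The median was -0.85 (adjusted p = 0.00482, adjusted p = 0.280 with an estimated correlation). Amacr (-3.07 ± 0.27), the sterol 12-hydroxylase Cyp8b1 (-2.83 ± 0.25) and the rate-limiting Cyp7a1 (-2.04 ± 0.37) fell and the oxysterol hydroxylase Cyp7b1 rose (4.51 ± 0.63). Cholesterol and fatty acid synthesis (41 measured) counted 3 higher, 12 lower and 26 not called, with 6 and 17 adjusted over the list alone. Their median lay at -0.73 (adjusted p = 0.00319, adjusted p = 0.667 with an estimated correlation). Insig2 (-1.97 ± 0.34), the synthase Hmgcs1 (-1.82 ± 0.33) and the lipogenic regulator Srebf1 (-1.73 ± 0.32) fell. For fatty acid oxidation and ketogenesis (33 measured) the counts were 2 higher, 7 lower and 24 not called, with 2 and 7 adjusted over the list alone. The list's median was -0.31 (adjusted p = 0.0187, adjusted p = 0.562 with an estimated correlation). Angptl4, a lipase inhibitor, fell (-1.38 ± 0.38) and Pex11a, a peroxisome proliferation factor, rose (3.38 ± 0.30). Pericentral hepatocyte markers fell with a median of -0.71 (adjusted p = 0.0138, adjusted p = 0.280 with an estimated correlation). Of 14 measured, 1 rose, 7 fell and 6 were not called, with 1 and 7 adjusted over the list alone. Those that fell included the Wnt target Axin2 (-1.53 ± 0.30) and Tbx3 (-2.23 ± 0.52), while glutamine synthetase, Glul, rose (1.34 ± 0.31). Blocked and slide 5 medians were -0.94 and -1.01 for bile acids, -0.67 and -0.72 for cholesterol, -0.41 and -0.29 for oxidation and -0.79 and -1.30 for pericentral markers. The oxidation list was lost without male vehicle 2 (adjusted p = 0.0930) or male dexamethasone 2 (0.0628), and that of Angptl4 (0.0888 without male vehicle 2) was lost likewise.

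Cell cycle, clock and stress genes changed singly in males, and their lists as a whole were not called. Cyclin D1, Ccnd1, fell (-3.20 ± 0.42) while cyclin E1, Ccne1 (4.67 ± 0.20), and the cyclin kinase inhibitor Cdkn1a (5.02 ± 0.24) rose. The clock output gene Dbp fell (-2.78 ± 0.49) and the repressor Cry1 rose (1.94 ± 0.23). Immediate early Egr1 fell (-2.72 ± 0.36) and the inducible chaperone Hspa1a rose (2.91 ± 0.20). The acute phase proteins alpha-2-macroglobulin, A2m (2.66 ± 0.55), and orosomucoid, Orm1 (3.05 ± 0.46), rose, whereas Mbl2 (-1.37 ± 0.26) and Kng1 (-1.15 ± 0.31) fell, and leaving out a single array ended the call of Kng1 (0.0841 without male dexamethasone 3). Cidea, a lipid droplet gene, rose (3.55 ± 0.27), and so did the reductase Por (2.33 ± 0.23) and Ppp1r3c, a glycogen-targeting subunit (3.15 ± 0.31). Urea cycle Ass1 rose (2.01 ± 0.17), as did the endothelial marker Lyve1 (1.66 ± 0.36) and the chaperone Hspa8 (1.35 ± 0.18). Camera called none of the lists of cell cycle (3 higher, 2 lower of 32; median 0.18, 0.24 with the block, 0.14 within slide 5, adjusted p = 0.320), circadian clock (4 and 4 of 19; median -0.04, 0.02 with the block, -0.29 within slide 5, adjusted p = 0.936), immediate early and heat shock genes (7 and 6 of 30; median 0.27, 0.42 with the block, 0.82 within slide 5, adjusted p = 0.235) or acute phase proteins (2 and 2 of 31; median -0.05, -0.22 with the block, -0.18 within slide 5, adjusted p = 0.885). It also left out xenobiotic metabolism and transport (5 and 5 of 37; median -0.40, -0.35 with the block, -0.58 within slide 5, adjusted p = 0.515), growth hormone, IGF and insulin signalling (5 and 5 of 35; median -0.13, -0.21 with the block, -0.13 within slide 5, adjusted p = 0.931) and steroid receptors and chaperones (3 and 1 of 28; median 0.15, 0.12 with the block, 0.08 within slide 5, adjusted p = 0.563). Igf1 itself was not called (0.07 ± 0.30). Among cell-type lists camera passed over stellate cells (median 0.12, 0.10 with the block, 0.14 within slide 5, adjusted p = 0.931), endothelial cells (median 0.07, 0.01 with the block, -0.03 within slide 5, adjusted p = 0.931), erythroid cells (median -0.49, -0.49 with the block, -0.84 within slide 5, adjusted p = 0.216), adipocytes (median 0.81, 0.58 with the block, 0.69 within slide 5, adjusted p = 0.129), exocrine pancreas (median 0.33, 0.21 with the block, 0.35 within slide 5, adjusted p = 0.931) and periportal hepatocytes (median 0.12, 0.19 with the block, 0.27 within slide 5, adjusted p = 0.201).

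Sex-biased liver genes fell as lists in males after dexamethasone, while the best-known members were not called. Of 30 measured female-biased genes, 1 rose, 8 fell and 21 were not called, with 1 and 9 adjusted over the list alone. The median change was -0.76 (adjusted p = 0.00170, adjusted p = 0.280 with an estimated correlation). Those that fell included the sulfotransferases Sult2a1 (-3.49 ± 0.56) and Sult2a2 (-1.63 ± 0.48). Of 28 male-biased genes, 1 rose, 6 fell and 21 were not called, with 1 and 7 adjusted over the list alone. Together they had a median of -0.49 (adjusted p = 0.00803, adjusted p = 0.402 with an estimated correlation). Members that fell were Spink1 (-3.63 ± 0.29), Stac3 (-2.84 ± 0.60) and the hydroxyacid oxidase Hao2 (-2.16 ± 0.32). The male-specific Cyp2c11 (-0.60 ± 0.38, adjusted p = 0.333) and the female-specific Cyp2c12 (-0.57 ± 0.53, adjusted p = 0.531) were not called. The male-biased result was lost without male vehicle 3 (adjusted p = 0.0519) or male dexamethasone 2 (0.0529), and the call of Sult2a2 (0.113 without male dexamethasone 2) was lost likewise. Medians were -0.61 with slide as a block and -0.89 within slide 5 for male-biased genes and -1.004 with slide as a block and -1.03 within slide 5 for female-biased genes.

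**Figure D1:**
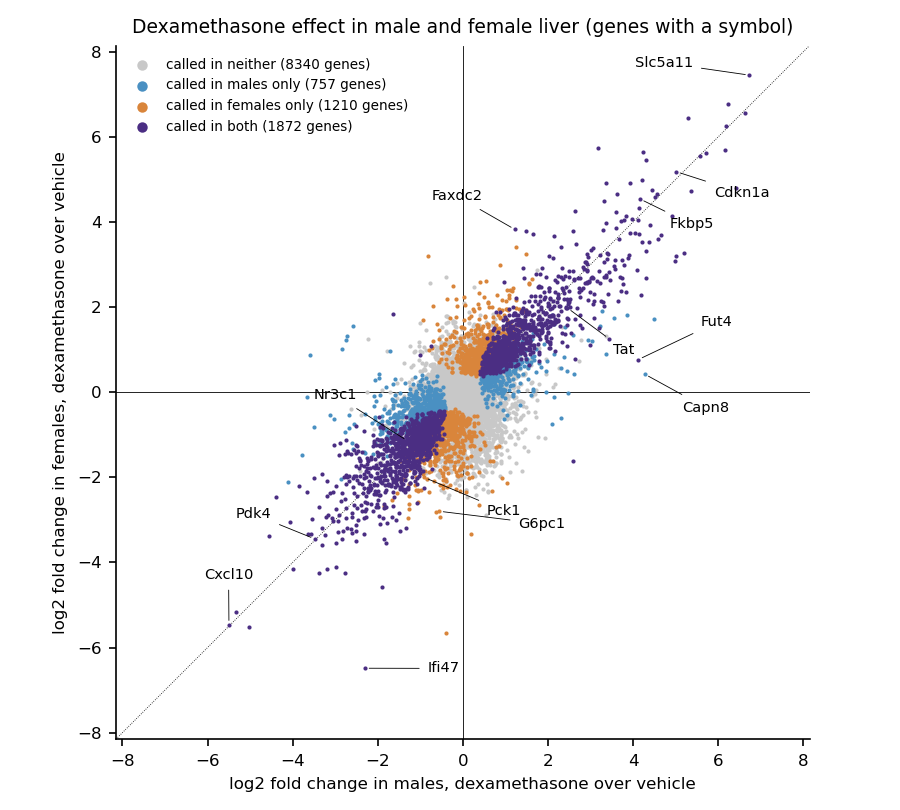
Log2 change by dexamethasone in females (vertical axis) against males (horizontal axis), with 1 point per gene with a symbol (12179 genes, 3 arrays per group), coloured by the sex or sexes in which it was called. Most called genes lie near the diagonal, for example Fkbp5 (4.17 in males and 4.54 in females), while Fut4 (4.13 and 0.77) lies away from it.

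In female liver the same glucocorticoid-responsive genes rose. Fkbp5 increased 23.3-fold (4.54 ± 0.20, adjusted p = 3.74e-06), Tsc22d3 7.16-fold (2.84 ± 0.24), Per1 6.55-fold (2.71 ± 0.17) and Tat 3.95-fold (1.98 ± 0.32, adjusted p = 0.00153). Nr3c1 fell again (-1.14 ± 0.17), and the mineralocorticoid receptor Nr3c2 fell too (-1.39 ± 0.18). In total 5919 genes differed from vehicle in females, 2850 higher and 3069 lower, and 3526 of them differed at least 2-fold.

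The largest changes in females overlapped with those in males. Slc5a11 rose at least 60.5-fold, B3galnt1 at least 30.2-fold, Tekt5l1 at least 25.8-fold, Doc2a at least 25.4-fold and Gucy2c at least 23.3-fold. Ces2c (6.77 ± 0.41), Aspa (5.63 ± 0.39), Slc4a8 (5.55 ± 0.19), the retinol dehydrogenase Rdh16 (5.74 ± 0.45) and the BH3-only cell death gene Hrk (5.64 ± 0.60) increased as well. The interferon-inducible GTPase Ifi47 fell most (-6.49 ± 0.60, adjusted p = 6.66e-05), and Osgin1 (-5.53 ± 0.30) and Gucy1b2 (-5.16 ± 0.43) also fell. Further large decreases were those of Cxcl10 (at least 13.0-fold), the nociceptin precursor Pnoc (at least 8.64-fold), Ccl2 (at least 4.37-fold), Cyp26b1 (at least 5.47-fold), Dbp (-4.24 ± 0.49) and Ccnd1 (-4.16 ± 0.42). All 122 named or nameable genes kept their direction with slide as a block (89 still called) and 121 did within slide 5. Agreement within slide 5 was again largely fixed by the lack of overlap and is no test. The exception was Lyve1 (1.11 ± 0.36, adjusted p = 0.0456), at 0.06 with the block and -0.12 within slide 5. Its call was lost when an array was left out, as Lyve1 (0.161 without female vehicle 2) shows. With the block Fkbp5 was at 4.29 and Tat at 2.07.

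As lists, glucose and amino acid genes rose in females, although some members fell. Of 31 glucocorticoid-induced genes, 17 rose, 4 fell and 10 were not called, with 17 and 5 adjusted over the list alone. The median was 1.13 (adjusted p = 9.45e-05, adjusted p = 0.0317 with an estimated correlation). Of 32 genes of gluconeogenesis and amino acid catabolism, 15 rose, 3 fell and 14 were not called, with 18 and 3 adjusted over the list alone. The median log2 change was 0.81 (adjusted p = 6.32e-05, adjusted p = 0.175 with an estimated correlation). Pfkfb1 (4.27 ± 0.31), Tdo2 (3.24 ± 0.18), Got1 (3.12 ± 0.17) and Sds (1.82 ± 0.38) rose. Against the list's name, the glucose-6-phosphatase G6pc1 (-2.80 ± 0.26, adjusted p = 6.66e-05) and Pck1 (-2.002 ± 0.40, adjusted p = 0.00490) fell. The interaction test gave adjusted p = 0.542 for Pck1 and adjusted p = 0.0883 for G6pc1, which was not called in males (-0.56 ± 0.26). Pck1 lay at -1.51 with slide as a block and at -1.36 within slide 5. Insulin receptor substrate Irs2 fell (-2.24 ± 0.29) and the transcription factor Foxo3 rose (2.16 ± 0.33), beside higher Ppp1r3c (2.63 ± 0.31), Ass1 (2.02 ± 0.17) and the urea cycle synthetase Cps1 (2.18 ± 0.58). The call of Cps1 (0.0802 without female dexamethasone 2) was lost when an array was left out. The median for gluconeogenesis was 0.66 with genes at their bound, and 0.93 with slide as a block and 1.01 within slide 5. That of the glucocorticoid-induced genes was 1.13 with slide as a block and 1.17 within slide 5.

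Inflammatory and interferon genes fell in females too. Of 30 interferon-response genes, 1 rose, 19 fell and 10 were not called, with 1 and 21 adjusted over the list alone. The median was -1.20 (adjusted p = 2.54e-06, adjusted p = 0.136 with an estimated correlation). It was -0.88 when genes below background were set at their bound and -1.45 with slide as a block and -1.23 within slide 5. Guanylate-binding Gbp2 fell (-3.19 ± 0.26) and Ifih1 rose (4.06 ± 0.21) as in males. Of 33 inflammatory mediators, 4 rose, 16 fell and 13 were not called, with 4 and 19 adjusted over the list alone. Their median stood at -0.79 (adjusted p = 1.92e-04, adjusted p = 0.136 with an estimated correlation). Examples were Il1b (-2.79 ± 0.30) and the chemokine Ccl4 (-2.17 ± 0.23). Outside this list, in that of immediate early and heat shock genes, the stress cytokine Gdf15 fell (-3.27 ± 0.38) and Zfp36 rose (2.39 ± 0.54). Of 24 antigen-presentation genes, 0 rose, 10 fell and 14 were not called, with 0 and 12 adjusted over the list alone. As a list they had a median of -0.59 (adjusted p = 5.45e-04, adjusted p = 0.0524 with an estimated correlation). The largest decreases were those of the class II genes RT1-Bb (-1.95 ± 0.40), RT1-Da (-1.86 ± 0.30) and RT1-Db1 (-1.63 ± 0.26). Medians were -0.93 with slide as a block and -1.07 within slide 5 for mediators and -0.45 with slide as a block and -0.52 within slide 5 for antigen presentation.

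Among cell-type markers in females, lymphocyte, neutrophil, stellate and bile duct lists fell and adipocyte genes rose. Of 16 T and NK markers, 0 rose, 11 fell and 5 were not called, with 0 and 13 adjusted over the list alone. The list had a median of -1.16 (adjusted p = 6.06e-05, adjusted p = 0.136 with an estimated correlation), or of -0.9996 with genes at their bound. Members that fell were Gzma (-2.41 ± 0.23), the lymphotoxin gene Ltb (-1.65 ± 0.32) and Cd3g (-1.62 ± 0.32). Of 7 neutrophil markers, 0 rose, 4 fell and 3 were not called, with 0 and 5 adjusted over the list alone. The list had a median of -2.09 (adjusted p = 0.0158, adjusted p = 0.175 with an estimated correlation), or of -0.54 at the bound. Among them were the alarmins S100a8 (-3.21 ± 0.61) and S100a9 (-2.96 ± 0.48) and the oxidase subunit Ncf1 (-2.44 ± 0.39). Of 16 stellate cell and fibroblast markers, 0 rose, 4 fell and 12 were not called, with 0 and 6 adjusted over the list alone. The median was -0.37 (adjusted p = 0.0243, adjusted p = 0.552 with an estimated correlation). Members that fell were Pdgfrb (-2.30 ± 0.28), a growth factor receptor, and Lrat, which stores vitamin A (-2.15 ± 0.20). Without female dexamethasone 3 the stellate list was lost (adjusted p = 0.205). Of 13 bile duct markers, 0 rose, 4 fell and 9 were not called, with 0 and 4 adjusted over the list alone, Krt7 (-1.65 ± 0.31) and Krt18 (-1.65 ± 0.27) among those that fell. The list had a median of -0.67 (adjusted p = 0.0238, adjusted p = 0.164 with an estimated correlation) and was lost with the slide block (adjusted p = 0.121). Adipocyte genes, 8 measured, gave 3 higher, 0 lower and 5 not called, with 3 and 0 adjusted over the list alone (median 0.68, adjusted p = 0.0401, adjusted p = 0.168 with an estimated correlation), with higher Cidea (2.98 ± 0.27) and Cidec (1.66 ± 0.20), genes of lipid droplets. They were lost with the slide block (adjusted p = 0.197) and without female vehicle 3 (0.0775), female dexamethasone 1 (0.0534) or female dexamethasone 2 (0.0651). With the block and within slide 5 the medians were -1.37 and -1.40 for T and NK markers, -1.89 and -1.64 for neutrophils, -0.72 and -0.81 for stellate cells, -0.27 and -0.36 for bile duct cells and 0.68 and 0.93 for adipocytes. Kupffer (median -0.55, -1.42 with the block, -1.45 within slide 5, adjusted p = 0.179) and B cell markers (median -0.59, -0.96 with the block, -0.88 within slide 5, adjusted p = 0.213) were not called as lists. The Kupffer list was called with the slide block (adjusted p = 6.03e-05), which was run at the preset correlation alone. Tyrobp (-1.38 ± 0.28), Aif1 (-1.31 ± 0.38) and Cd79b (-2.43 ± 0.58) fell singly. Without a single array the calls of Cd79b (0.0550 without female dexamethasone 2) and Aif1 (0.1004 without female vehicle 1) were lost. The endothelial growth factor receptor Kdr fell as well (-2.29 ± 0.37), in a list that was not called (median -0.25, -0.23 with the block, -0.12 within slide 5, adjusted p = 0.376).

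Lipid, bile acid and sex-biased lists were not called in females, although single members changed. Hmgcs1 (-2.34 ± 0.33), Mvd (-1.97 ± 0.38) and Fdps (-1.44 ± 0.32) of sterol synthesis fell in a list with 2 higher, 10 lower and 29 not called, with 2 and 11 adjusted over the list alone (median -0.63, -0.25 with the block, -0.30 within slide 5, adjusted p = 0.0637). Cyp8b1 (-3.45 ± 0.25), Amacr (-2.95 ± 0.27) and the conjugating enzyme Baat (-1.66 ± 0.24) fell and Cyp27a1 rose (1.35 ± 0.16) among bile acid genes (2 higher, 5 lower and 18 not called, with 2 and 6 adjusted over the list alone, median -0.45, -0.22 with the block, -0.004 within slide 5, adjusted p = 0.162). The fatty acid gatekeeper Cpt1a (-1.48 ± 0.22), Fgf21 (-3.39 ± 0.91) and Pdk4 (at least 9.14-fold lower) fell and Pex11a rose (3.29 ± 0.30) within fatty acid oxidation (2 higher, 10 lower and 21 not called, with 2 and 12 adjusted over the list alone, median -0.48, -0.07 with the block, -0.03 within slide 5, adjusted p = 0.145). Female-biased genes counted 2 higher, 6 lower and 22 not called, with 2 and 6 adjusted over the list alone (median -0.36, -0.11 with the block, 0.03 within slide 5, adjusted p = 0.213), with lower Cux2, a female-specific repressor (-3.46 ± 0.46), and Trim24 (-2.81 ± 0.28). Male-biased genes counted 1 higher, 4 lower and 23 not called, with 1 and 4 adjusted over the list alone (median -0.03, 0.39 with the block, 0.68 within slide 5, adjusted p = 0.715), with lower Spink1 (-3.33 ± 0.29) and Hao2 (-2.25 ± 0.32) and higher Bcl6 (2.67 ± 0.62), a repressor of female-biased genes. Cyp2c11 (-0.27 ± 0.34) and Cyp2c12 (-0.41 ± 0.53) were not called. Of the remaining lists camera called neither acute phase proteins (median -0.03, -0.10 with the block, -0.21 within slide 5, adjusted p = 0.900, mean 0.06 with the test pointing up; A2m rose by 3.496 ± 0.55 and Orm1 by 2.69 ± 0.46) nor the circadian clock (median -0.47, -0.26 with the block, -0.002 within slide 5, adjusted p = 0.715). Cell cycle genes (median 0.39, 1.09 with the block, 0.95 within slide 5, adjusted p = 0.184) were called only with the slide block (adjusted p = 6.03e-05), at the preset correlation. Not called either way were immediate early and heat shock genes (median 0.13, -0.09 with the block, 0.04 within slide 5, adjusted p = 0.612) and growth hormone, IGF and insulin signalling (median -0.05, 0.13 with the block, 0.10 within slide 5, adjusted p = 0.758). Nor were shifts called for steroid receptors and chaperones (median 0.03, 0.13 with the block, -0.002 within slide 5, adjusted p = 0.269) or xenobiotic metabolism and transport (median -0.07, 0.10 with the block, 0.06 within slide 5, adjusted p = 0.511). Pericentral (median -0.54, -0.37 with the block, -0.45 within slide 5, adjusted p = 0.0907) and periportal hepatocytes (median 0.33, 0.22 with the block, 0.29 within slide 5, adjusted p = 0.0907) were not called, nor were erythroid cells (median -0.51, 0.13 with the block, -0.30 within slide 5, adjusted p = 0.376) or exocrine pancreas (median -0.44, 0.05 with the block, 0.14 within slide 5, adjusted p = 0.612). Within them Cdkn1a (5.19 ± 0.24), Ccne1 (3.71 ± 0.20), Hspa1a (2.59 ± 0.20), the clock activator Bmal1 (1.61 ± 0.50), Cry1 (1.62 ± 0.23), the sulfotransferase Sult1a1 (2.68 ± 0.18) and Por (2.92 ± 0.23) rose, and Egr1 fell (-2.001 ± 0.36). Without a single array the calls of Fgf21 (0.0782 without female vehicle 1) and Bmal1 (0.107 without female vehicle 3) were lost.

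**Figure D2:**
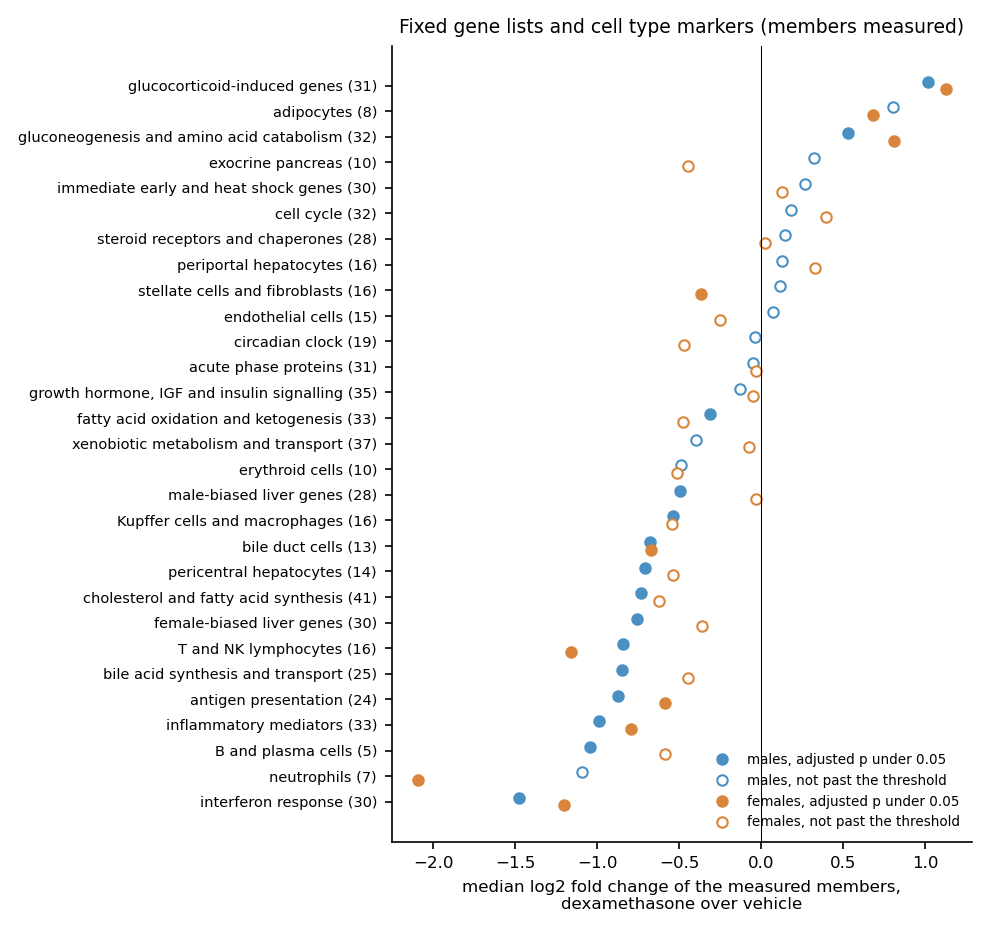
Median log2 change by dexamethasone (horizontal axis) of each gene list (vertical axis) in males and females, 3 arrays per group, with filled marks where camera called the list. Glucocorticoid-induced genes lie at 1.02 in males and 1.13 in females, and interferon-response genes at -1.48 and -1.20.

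The responses of the sexes to dexamethasone overlapped in part. Of 7427 genes called in either sex 4040 were called in a single sex. In both sexes 1624 genes rose, where independent calls would give 266.1, and 1756 fell, where they would give 331.7. Across all genes the male and female changes correlated at Pearson r = 0.69, and across the genes called in either sex at 0.84, although genes are not independent replicates. Of 1508 genes called in males only, 1349 (89.5%) had a change of the same sign in females and 533 (35.3%) had it at an unadjusted p under 0.05. Of 2532 called in females only, 2182 (86.2%) had the same sign in males and 825 (32.6%) had it at that p. The interaction test passed 5 of those genes and 2 genes called in both sexes. Another 7 genes were called in opposite directions, with interaction adjusted p from 0.0883 to 0.151, among them, chosen after its values were seen, the growth factor receptor Egfr (-1.01 in males, 0.88 in females). On slide 5 alone 97.4% of the genes called in males from the other 8 arrays kept their direction, and 86.0% of those called in females.

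The dexamethasone effect itself differed between the sexes for 7 genes. Capn8, a calpain protease gene, stood above background after dexamethasone in males alone, where it rose at least 6.67-fold (interaction adjusted p = 0.0360), so the size of its difference was not measured. Fut4, a fucosyltransferase of cell-surface glycans, rose by 4.13 in males and by 0.77 in females (difference -3.36 ± 0.36, adjusted p = 0.0360). Faxdc2, of the fatty acid hydroxylase family, rose more in females (3.83) than in males (1.22; difference 2.61 ± 0.30, adjusted p = 0.0360). Among the 7 were 3 probes without a gene name, of which 2 differed by 2.08 and -3.14 on the log2 scale and 1 lay below background in 2 groups. With slide as a block adjusted p was 0.126 for each of Capn8, Fut4 and Faxdc2, so none stayed called. The differences were then -3.98 for Fut4 and 2.55 for Faxdc2, and within slide 5 -3.67 and 2.29. Leaving out a single array ended the calls of Capn8 (0.137 without female dexamethasone 1), Fut4 (0.102 without female vehicle 1) and Faxdc2 (0.137 without female dexamethasone 1), with 0 to 5 genes called in all. At an unadjusted p under 0.05 there were 2433 genes, where chance alone gives 1215.

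**Figure D3:**
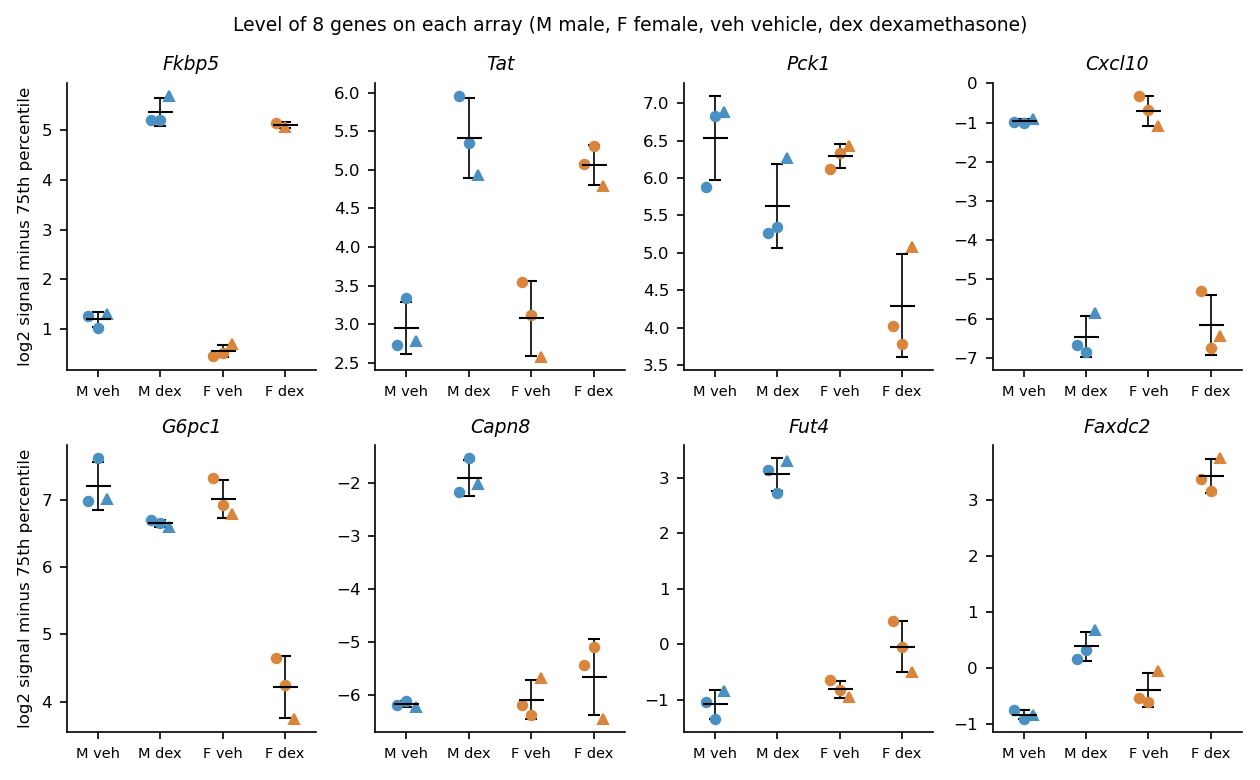
Normalized log2 intensity (vertical axis) in the 4 groups for Fkbp5, Tat, Pck1, Cxcl10, G6pc1, Capn8, Fut4 and Faxdc2, with 1 mark per array (triangles on slide 5, circles elsewhere) and bars giving the group mean ± SD. Cxcl10 after dexamethasone, and Capn8 except in males after dexamethasone, lay below background. Fut4 differs between the sexes by -3.36 in its response, and Fkbp5 by 0.38.

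Among gene lists, 3 differed between the sexes in the response to dexamethasone. Stellate cell and fibroblast markers were lower in the female than in the male response, with a median difference of -0.60 (adjusted p = 0.00374, adjusted p = 0.850 with an estimated correlation), and -0.79 with slide as a block and -0.93 within slide 5. They were lost without female dexamethasone 3 (adjusted p = 0.109). Male-biased liver genes had a higher female than male response, by a median of 0.47 (adjusted p = 0.0243, adjusted p = 0.850 with an estimated correlation), and 0.87 with slide as a block and 1.52 within slide 5. They were lost without male dexamethasone 2 (0.112), female vehicle 3 (0.347) or female dexamethasone 3 (0.109). Their median change was -0.49 in males and -0.03 in females, and -0.61 and 0.39 with the block. After vehicle these genes already lay lower in females (median -4.35). Xenobiotic genes had a higher female than male response as well, by a median of 0.27 (adjusted p = 0.0409, adjusted p = 0.850 with an estimated correlation), and 0.44 with slide as a block and 0.61 within slide 5. They were lost in 8 of 12 runs without 1 array, without male vehicle 2 (0.0946) or 3 (0.231), male dexamethasone 2 (0.0888) or 3 (0.154), female vehicle 3 (0.303) or female dexamethasone 1 (0.0749), 2 (0.0528) or 3 (0.0711). The interaction test called none of the classical genes, Fkbp5 (0.38 ± 0.27, adjusted p = 0.640), Tat (-0.48 ± 0.45, adjusted p = 0.717), Per1 (-0.33 ± 0.23), Tsc22d3 (-0.36 ± 0.33) and Pck1 (-1.10 ± 0.56). With slide as a block 6 further lists were called, with higher values in the female response for cell cycle (0.76, adjusted p = 0.00329), fatty acid oxidation (0.50, 0.00332), female-biased genes (0.68, 0.00341) and bile acids (0.48, 0.0434), and lower ones for Kupffer cells (-0.76, 0.0210) and T and NK markers (-0.55, 0.0263). Without the block their medians were 0.20, 0.05, 0.45, 0.28, 0.18 and -0.32. All 6 calls rest on the preset correlation. With an estimated correlation and no block, 0 of 29 lists were called for the interaction. The glucocorticoid-induced list was not called (median -0.23, -0.08 with the block, -0.51 within slide 5, adjusted p = 0.536). Simulated data recovered an effect of 4-fold present in males only in 33.0% of genes by the interaction test, and an effect of 2-fold in 0.299%, so most sex differences of that size would have gone uncalled.

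Without dexamethasone, male and female livers differed strongly in the known sex-biased genes. The male-specific cytochrome P450 Cyp2c11 was lower in females (-8.88 ± 0.38, adjusted p = 5.18e-06), as was its relative Cyp2c13 (-8.90 ± 0.47), and the female-specific Cyp2c12 was higher (3.97 ± 0.53, adjusted p = 0.00278). The steroid dehydrogenase Hsd3b5 was at least 484-fold lower, the urinary protein genes Obp3 at least 275-fold and Mup4 at least 234-fold and the estrogen sulfotransferase Sult1e1 at least 129-fold lower in females. Sult1e1 had been placed in the female-biased list and so went against it. Among 24298 genes 180 were higher and 235 lower in females, and 358 of these differed at least 2-fold. Further male-predominant genes were Mup4l3 (-9.65 ± 0.95), Mup4l1 (-9.33 ± 1.01), Mup4l4 (-8.85 ± 0.86), Stac3 (-8.34 ± 0.60), Cyp3a2 (-6.49 ± 1.17), Cyp3a18 (-3.96 ± 0.51) and Hsd11b1, which regenerates active glucocorticoid (-2.62 ± 0.25). Genes higher in females included the aldo-keto reductases Akr1b7 (11.75 ± 1.001) and Akr1b8 (8.27 ± 0.45), A1bg (11.50 ± 1.195), Adh1-ps1 (at least 91.5-fold), the prolactin receptor Prlr (7.31 ± 0.99), Cux2 (6.32 ± 0.46), the cytokine receptor Lifr (6.11 ± 0.53), Rasd2 (5.398 ± 0.38), the fatty acid transporter Cd36 (2.88 ± 0.59) and Ifi47 (4.51 ± 0.60). The pancreatic carboxypeptidase Cpa1 was at least 20.7-fold higher in female liver, whereas the elastase Cela1 was lower (-2.01 ± 0.36). The glucocorticoid-inducible kinase Sgk1 was lower in females (-2.19 ± 0.28), as were Pfkfb1 (-2.01 ± 0.31), the nuclear receptor Nr1i3 (-1.60 ± 0.26) and Gstm1 (-1.55 ± 0.20). Of 4 sex chromosome genes measured, Utx (0.87 ± 0.14) and Eif2s3 (0.75 ± 0.13) were higher in females. Fkbp5 was not called (-0.63 ± 0.18). Leaving out a single array ended the calls of Cela1 (0.0840 without male vehicle 3), Cd36 (0.131 without female vehicle 1), Cyp3a2 (0.0747 without male vehicle 3), Utx (0.0620 without female vehicle 1) and Eif2s3 (0.0637 without female vehicle 1).

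Of 28 measured male-biased genes, 0 were higher, 19 lower and 9 not called, with 0 and 23 adjusted over the list alone. The median difference was -4.35 (adjusted p = 6.78e-51, adjusted p = 0.00249 with an estimated correlation), with -4.27 with slide as a block and -4.63 within slide 5. Of 30 female-biased genes, 13 were higher, 3 lower and 14 not called, with 15 and 6 adjusted over the list alone. Their median difference was 0.90 (adjusted p = 1.34e-07, adjusted p = 0.174 with an estimated correlation), with 0.61 with slide as a block and 0.66 within slide 5. A smaller shift was called for 37 xenobiotic genes (0 higher, 6 lower and 31 not called, with 5 and 12 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.0105, adjusted p = 0.809 with an estimated correlation), with -0.36 with slide as a block and -0.62 within slide 5, and the call was lost without male vehicle 3 (adjusted p = 0.219). Another was called for 24 antigen-presentation genes (0 higher, 0 lower and 24 not called, with 2 and 0 adjusted over the list alone). Their median was 0.25 (adjusted p = 0.00991, adjusted p = 0.125 with an estimated correlation), with 0.33 with slide as a block and 0.34 within slide 5, and the call was lost without male vehicle 1 (0.0766) or female vehicle 1 (0.0785). Acute phase genes were called with a median of 0.24 (adjusted p = 0.0435, adjusted p = 0.809 with an estimated correlation), and 0.18 with slide as a block and 0.32 within slide 5. They were lost with the slide block (adjusted p = 0.182) and without male vehicle 1 (0.934), male dexamethasone 2 (0.0511), female vehicle 3 (0.482) or female dexamethasone 3 (0.0615). Erythroid markers had a median of -0.49 (adjusted p = 0.0236, adjusted p = 0.809 with an estimated correlation), and -0.33 with slide as a block and 0.01 within slide 5. They were lost with the slide block (adjusted p = 0.158) and without male vehicle 1 (0.113), female vehicle 1 (0.0737) or female vehicle 2 (0.0839). Called only with the slide block were the interferon-response (median 0.21, adjusted p = 0.00998, against 0.08 without) and cholesterol lists (0.32, 0.00998, against 0.12). Both were run with the block at the preset correlation alone. Exocrine pancreas genes were not called as a list (2 higher, 1 lower and 7 not called, with 3 and 1 adjusted over the list alone, median 0.35, 0.39 with the block, 0.48 within slide 5, adjusted p = 0.0540). Of 39 named or nameable genes all kept their direction with slide as a block (28 still called) and 38 did so within slide 5, where Cyp2c11 had no usable value. Since no called gene overlapped between the sexes, direction within slide 5 was fixed in advance and is no test. Cyp2c11 stood at -8.71 with the block.

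After dexamethasone 101 of the 180 genes higher in females after vehicle were called higher again, and 108 of the 235 lower genes lower. Ifi47 (0.32 ± 0.60) and Pfkfb1 (-0.37 ± 0.31) were no longer called. Cyp2c11 remained lower in females (-8.56 ± 0.34, adjusted p = 3.46e-06), as did Cyp2c13 (-8.71 ± 0.47), Obp3 (-8.74 ± 1.12), Mup5 (-8.49 ± 0.87), Mup4 (at least 219-fold), Hsd3b5 (at least 166-fold), Sult1e1 (at least 51.1-fold), Mup4l3 (-8.73 ± 0.95), Cyp3a2 (-6.33 ± 1.17) and Hsd11b1 (-2.49 ± 0.25). Cyp2c12 stayed higher (4.13 ± 0.53), with A1bg (12.69 ± 1.195), Akr1b7 (12.03 ± 1.001), Akr1b8 (6.97 ± 0.45), Adh1-ps1 (at least 67.5-fold), Prlr (7.69 ± 0.99), Cpa1 (at least 12.3-fold) and Cd36 (3.41 ± 0.59). In this condition 310 genes were higher and 251 lower in females, 470 of them by at least 2-fold. The sulfotransferases Sult2a1 (7.07 ± 0.56) and Sult2a2 (6.97 ± 0.48) and the retinoid-metabolizing Cyp2c7 (6.31 ± 1.03) were among the largest. Cyp7a1 was higher in females (2.70 ± 0.37, adjusted p = 0.00375), after a fall in males, with interaction adjusted p = 0.325. G6pc1 was lower in females (-2.43 ± 0.26, adjusted p = 7.59e-04), and so were Sgk1 (-2.51 ± 0.28), the stress factor Atf3 (-1.75 ± 0.38), cyclin E1, Ccne1 (-1.20 ± 0.20), and Lrat (-1.30 ± 0.20). Pck1 was not called (-1.33 ± 0.40, adjusted p = 0.132). Utx (0.81 ± 0.14) and Eif2s3 (0.82 ± 0.13) again were higher in females. Leaving out a single array ended the calls of Cyp3a2 (0.0668 without male dexamethasone 2), Cd36 (0.0560 without female dexamethasone 3), Atf3 (0.154 without female dexamethasone 1), Ccne1 (0.0550 without female dexamethasone 2) and Utx (0.0710 without female dexamethasone 1).

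Immune gene lists were called higher in females after dexamethasone, but not with slide as a block. Of 24 antigen-presentation genes, 3 were higher, 0 lower and 21 not called, with 4 and 0 adjusted over the list alone. The median difference was 0.23 (adjusted p = 0.00186, adjusted p = 0.0636 with an estimated correlation), with 0.13 with slide as a block and 0.22 within slide 5. Higher members were Tap1 (1.17 ± 0.24), Tap2 (0.74 ± 0.16) and the immunoproteasome subunit Psmb8 (1.63 ± 0.25). With the slide block the list gave adjusted p = 0.170. Of 30 interferon-response genes, 5 were higher, 0 lower and 25 not called, with 6 and 0 adjusted over the list alone. They differed by a median of 0.29 (adjusted p = 0.00753, adjusted p = 0.668 with an estimated correlation), with 0.27 with slide as a block and 0.34 within slide 5. Higher members were Igtp (1.51 ± 0.29) and the tetherin gene Bst2 (0.94 ± 0.18), beside Tap1, Tap2 and Psmb8, which belong to both lists. The interferon list was lost with the slide block (adjusted p = 0.0600) and without female dexamethasone 1 (0.0841). The RNA sensor Tlr3, of the inflammatory mediator list, was higher as well (1.47 ± 0.30). Of 31 acute phase proteins, 2 were higher, 0 lower and 29 not called, with 3 and 0 adjusted over the list alone. The median was 0.27 (adjusted p = 0.0137, adjusted p = 0.668 with an estimated correlation), with 0.20 with slide as a block and 0.20 within slide 5. The list held higher C4a (1.68 ± 0.37) and Kng1 (1.85 ± 0.31), and was lost with the slide block (adjusted p = 0.0600) and without female dexamethasone 3 (0.0656). The sex-biased lists stayed apart. Of 28 male-biased genes, 0 were higher, 19 lower and 9 not called, with 0 and 21 adjusted over the list alone, and the median was -3.75 (adjusted p = 3.91e-28, adjusted p = 0.0189 with an estimated correlation), with -3.49 with slide as a block and -3.75 within slide 5. Of 30 female-biased genes, 15 were higher, 2 lower and 13 not called, with 19 and 3 adjusted over the list alone, and the median was 1.03 (adjusted p = 4.97e-11, adjusted p = 0.0679 with an estimated correlation), with 1.42 with slide as a block and 1.57 within slide 5. Cholesterol and fatty acid synthesis was higher in females, with a median of 0.28 (adjusted p = 0.0319, adjusted p = 0.887 with an estimated correlation), and 0.64 with slide as a block and 0.62 within slide 5. It was lost without male dexamethasone 3 (0.637) or female dexamethasone 2 (0.177). Stellate markers were lower, with a median of -0.34 (adjusted p = 0.0101, adjusted p = 0.668 with an estimated correlation), and -0.57 with slide as a block and -0.57 within slide 5, and were lost without female dexamethasone 3 (0.310). With the slide block alone cell cycle genes were called higher (0.95, adjusted p = 4.54e-05, against 0.22 without) and endothelial markers lower (-0.33, 0.0453, against -0.20). Both calls were made at the preset correlation alone. All 49 named or nameable genes kept their direction with the slide block (30 still called) and within slide 5, where Cyp2c11 stood at -8.18. Direction within slide 5 was again fixed in advance by the lack of overlap. Lost when an array was left out were the calls of Tap1 (0.136 without female dexamethasone 2), Tap2 (0.150 without male dexamethasone 2), Tlr3 (0.121 without female dexamethasone 1), Igtp (0.0800 without male dexamethasone 2), Bst2 (0.0760 without male dexamethasone 1) and C4a (0.155 without female dexamethasone 2).

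**Figure D4:**
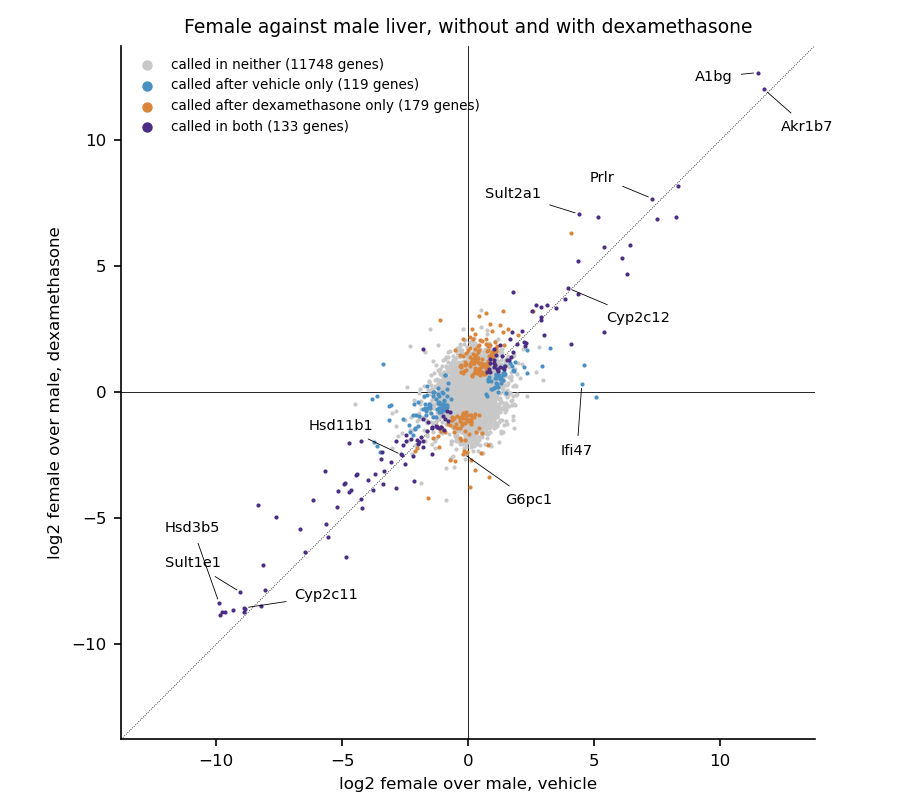
Log2 difference between females and males after dexamethasone (vertical axis) against that after vehicle (horizontal axis), with 1 point per gene with a symbol, 3 arrays per group, coloured by the condition in which it was called. Cyp2c11 lies at -8.88 and -8.56, and most called genes lie near the diagonal.

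Sex differences in the 2 conditions overlapped. After both vehicle and dexamethasone 101 genes were higher in females, where independent calls would give 2.3, and 108 were lower, where they would give 2.4, while 1 was called in opposite directions. Across all genes the differences correlated at Pearson r = 0.44 with a rank correlation of 0.04, and across the 766 genes called in either condition at 0.87, genes not being independent replicates. Called after vehicle only were 205 genes, and after dexamethasone only 351, of which 3 and 4 passed the interaction test. Within slide 5, 91.2% of the genes called from the other 8 arrays kept their direction after vehicle and 79.2% after dexamethasone.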

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

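The dexamethasone effect differed between the sexes for 7 genes, among them Capn8 (-3.85), Fut4 (-3.36), Faxdc2 (2.61) and 3 probes without a gene name (3.56, 2.08 and -3.14), each as the female minus the male log2 effect by the interaction test. Capn8 lay below background in 3 groups and the probe at 3.56 in 2, so those sizes rest partly on values below background. Among lists the median difference was 0.47 for male-biased liver genes, 0.27 for xenobiotic metabolism and transport and -0.60 for stellate cells and fibroblasts. With slide as a random block the adjusted p of the 7 genes ran from 0.0220 to 0.0642, and on the 8 arrays not on slide 5, a run chosen after the result was seen, none of the lists stayed called (adjusted p = 0.444, 0.561 and 0.368).

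The first pattern weighed is that 4040 genes were called by dexamethasone in a single sex while few passed the interaction test, and the draws without the mean sex difference were chosen after the result was seen. If both sexes respond alike and chance decides which sex passes, redrawn sex labels should often give as many genes at an unadjusted interaction p under 0.05. Of 100 draws, 15 gave at least the 2433 seen (highest other 4662). With each gene's mean sex difference removed first, 15 did so again (highest other 5857). The draws thus do not exclude this explanation, but they took no account of slides, whose arrays correlated at 0.512, so they are a limited test of it. If shared deviations of the arrays of a slide made the excess, it should shrink with slide as a random block. It did not, as the ratio to the number expected by chance was 2.84 (3446 genes, against 2433 without the block). This test cannot exclude slides, since a block also changes the standard errors and slide 4 held female dexamethasone arrays alone. The redrawn labels, which reached 4662 genes, also leave the number expected by chance without a firm footing. True differences between the sexes below the power of 3 arrays per group could also be present, as 33.0% of simulated 4-fold effects were recovered, and the cause stays open.

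The next pattern is the higher Cpa1 in females, for which both tests were chosen after the result was seen, with the males, below background, set at the dimmest value well above it. Pancreatic tissue taken with female livers would raise other exocrine genes by at least 2.19 on the log2 scale, yet the median of 9 others was 0.33 ± 0.37, which excludes it. A difference of single arrays or of a single slide would leave some slide or day without it. The lowest lower bound within a slide or scan day that held both sexes of a treatment was 3.25, on slide 5 after vehicle. On scan day 1 it was 5.37 after vehicle. As Cpa1 was picked as a called gene whose arrays do not overlap between the sexes, such agreement was largely fixed in advance and excludes nothing. Cpa1 rests on a single probe, so binding of another transcript to that probe could not be tested, and expression by female liver itself likewise stays open.

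The last pattern is the fall of interferon and antigen-presentation genes after dexamethasone, for which the tests on leukocytes and on Kupffer cells were chosen after the result was seen. Were it only a loss of leukocytes, the interferon list should fall no further than their 44 markers, and in females the difference of medians was -0.32 ± 0.33 (males -0.68 ± 0.36), so the test cannot tell. Against 16 Kupffer cell markers alone it was -0.65 ± 0.35 in females (males -0.94 ± 0.35), so that test cannot tell either. The gaps shrank within slides: with slide as a block they were -0.05 in females (males -0.36) for leukocytes and -0.03 (males -0.55) for Kupffer cells, and within slide 5 0.20 (males -0.06) and 0.21 (males -0.04). For slides, the lower of the sexes' ratios of the interferon list's median within slide 5 to that over all arrays was 0.809. That is a limited test which cannot exclude slides, since slide 5 holds 1 array per group and is itself part of all arrays. With slide as a block the list's median was -1.17 in males and -1.45 in females, so the fall was also seen in that model. Direct repression of these genes in hepatocytes could be told from fewer leukocytes only with cell-resolved data.

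For the numbers of genes called, 10 splits of 6 arrays are too few to exclude chance. The real grouping alone reached its own count, 1 of 10, with 4895 genes in males (highest other 0), 5919 in females (highest other 0), 415 between the sexes after vehicle (highest other 8) and 561 after dexamethasone (highest other 0). Chance can be excluded for the 3380 genes called in the same direction in both sexes, which 1 of 100 draws reached, the real one (highest other 0). By these draws chance can also be excluded for the 25 list calls in males and females, which 3 of 100 reached (highest other 28). The other draws called a median of 14 lists. Their redrawn groups still held more arrays of one treatment than of the other, and some draws kept the real split in 1 sex. That median is therefore no count of lists called without a treatment effect. The draws for both results took no account of slides, so they are a limited test. For the 7 genes of the interaction 4 of 100 draws gave as many, with a highest other of 831, over 100 times the real count. That points to structure of the samples, and with the mean sex difference removed the highest other was still 325. The 3 other draws that reached 7 all kept the dexamethasone arrays parted by sex, but so did 4 that called 0 to 2 genes, and slides as the source were not tested.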

How the results depend on the processing

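Genes called for the dexamethasone effect in males numbered 7745 with slide as a random block, and in females 3086 with slide as a fixed block. Those changed in both sexes came to 2099 with slide as a fixed block and 2243 with only the groups of the comparison in the fit. For the interaction the count was 28 with normexp background correction, 0 with no filter on dim probes, 4 with scan day as a block, 13 with eBayes trend and robust and 0 on the 8 arrays not on slide 5. The sex difference after vehicle gave 252 with slide as a fixed block, 654 with slide as a random block, 700 with scan day as a block, 165 with only the groups of the comparison and 263 on the 8 arrays not on slide 5. After dexamethasone it gave 919 with slide as a random block and 870 on the 8 arrays not on slide 5. List calls fell from 41 of 145 to 5 with an estimated correlation. Leaving out each array in turn gave 3679 to 5191 genes in males, 3744 to 6069 in females, 2526 to 3351 in both sexes, 0 to 5 for the interaction, 261 to 403 between the sexes after vehicle, 296 to 627 after dexamethasone and 35 to 44 list calls. Blocks and left-out arrays lower the residual degrees of freedom (4 with slide, 5 with scan day, 7 with an array left out), and beyond that the cause was not tested. The median of all genes lay at 0.12 in males and -0.20 in females with no filter on dim probes, and at 0.04 in females with slide as a fixed block, against 0.01 and -0.08 in the main run.

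Replicate numbers do not pair samples: 8 of 12 arrays correlated best with an array of their own number, but the excess lay in replicate 3, which shared a slide (median 0.36, against 0.07 and 0.08 for numbers 1 and 2). With replicate number as a block the counts were 6335 in males, 7731 in females, 4317 in both sexes, 8 for the interaction, 548 and 849 for the sex differences after vehicle and dexamethasone, and 41 list calls.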

Other observations

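Several carriers, signalling genes and red-cell genes not described above also responded to dexamethasone. Serpina7, which encodes thyroxine-binding globulin, fell in males (-1.69 ± 0.26) and females (-2.21 ± 0.26). Igfals, which stabilizes circulating IGF-1, fell in males (-1.20 ± 0.28), while the regulatory kinase subunit Pik3r1 rose (1.18 ± 0.20). Female arrays moved the same way. Their normalized log2 levels of Igfals were 4.76 to 5.06 after vehicle and 3.65 to 4.58 after dexamethasone. Those of Pik3r1 were -3.57 to -3.42 and -1.58 to -1.44. The red-cell membrane gene Epb42 fell in males (-1.51 ± 0.29) and in females (-1.06 ± 0.29), and the transferrin receptor Tfrc rose in males (1.55 ± 0.28) and in females (1.16 ± 0.28). In females the pancreatic protease gene Ctrb1 fell (-1.25 ± 0.33), the chaperone Hsp90aa1 rose (1.25 ± 0.40) and the estrogen receptor gene Esr1 rose at least 1.29-fold. Lost when an array was left out were the calls of Igfals (0.0515 without male vehicle 3) in males and of Epb42 (0.0899 without female dexamethasone 2), Tfrc (0.05 without female dexamethasone 2), Ctrb1 (0.0810 without female vehicle 2) and Hsp90aa1 (0.150 without female vehicle 1) in females.

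Some further sex differences held in both conditions. Tff3, a trefoil peptide of bile duct cells, was higher in females after vehicle (2.22 ± 0.39) and after dexamethasone (2.004 ± 0.39). It is also a member of the female-biased list and is counted there. The cyclin kinase inhibitor Cdkn1c, outside the sex-biased lists, was higher in females too (1.03 ± 0.22 and 1.02 ± 0.22). Called only after dexamethasone were the sterol sensor partner Scap and the clock receptor Rora, lower in females (-0.90 ± 0.16 and -1.28 ± 0.24), against 0.44 ± 0.16 and -0.48 ± 0.24 after vehicle. Without a single array the calls of Tff3 (0.0655 without male vehicle 3) and Cdkn1c (0.147 without male vehicle 1) after vehicle and of Tff3 (0.0903 without female dexamethasone 1), Cdkn1c (0.147 without female dexamethasone 1), Scap (0.0657 without female dexamethasone 1) and Rora (0.0831 without female dexamethasone 2) after dexamethasone were lost.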
